A study of Mus musculus with 12 samples.

How the data were processed

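Gene expression was measured by RNA sequencing in 12 mouse macrophage libraries, 4 groups of 3 replicates, with group, dose and hours taken from the labels. Each library has 1 deposited file that lists genes with a transcript length, an expected count and an FPKM. Per the submitters' processing notes, HISAT2, StringTie, Bowtie2 and RSEM were used with the builds GRCm39 and mm39, and no versions are given. The first unit is deposited expected counts, per the file headers: estimated reads or fragments per gene, of which 90.62 to 92.03% are whole numbers in each library. The second unit is deposited FPKM, per the file headers: expected counts divided by the transcript length and by the total count of the library. FPKM denominators recomputed from the values lay within -0.23 to 0.52% of the library totals, so no scaling beyond the library total was found in them. A gene missing from a file was taken as 0; 16145 genes are in at least 1 file and 12408 in all 12. Genes were named by the symbols of the files. The reference annotation, build GRCm38.p6, served only for gene positions and synonyms.

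The main test was run on expected counts rounded to whole numbers, in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, which left 12148, and scaled with TMM; the factors were 0.944 to 0.950 for 4-OI and 1.033 to 1.050 for wild-type vehicle. All 12 libraries entered 1 fit with a coefficient per group, and each comparison used the edgeR quasi-likelihood F test with robust dispersion. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error is the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 4.71%. Library totals ranged from 9405112 to 22390882 expected counts, and replicate pairs varied 2.40 to 4.88 times as much as counting alone gives (chi-square per degree of freedom). In a self-test on simulated data with 200 planted genes, the test found 66 to 80% of genes planted at a log2 fold change of 0.5 and 90 to 94% of those at 1, with 7 to 12 false calls a comparison. The planted genes were few beside those called in the data and were as often higher as lower. The self-test therefore does not show how the test or the scaling performs when many genes change.

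The groups, the tests of expression, their alternatives and 36 gene lists were fixed before the data were examined. The lists hold 593 symbols, of which 519 matched the files, 7 of them through a synonym. Some lists share genes, so their tests are not independent. Slc7a11 and Gss are in both the NRF2 and the ferroptosis lists. Sqstm1 is in both the NRF2 and the lysosome and autophagy lists. Hmox1 and Slc48a1 are in both the NRF2 and the heme breakdown lists. Lists with at least 3 tested members, 30 in all, were tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of a comparison. For each list, members were counted by adjusted p over all genes and adjusted over the list alone. Genes were named by a rule: Acod1, Hmox1 and Nqo1 always, the 8 called genes with the highest and the 8 with the lowest fold change among those with a mean of at least 5 CPM and no overlap between groups, leaving out provisional gene names, and up to 4 members per described list in order of adjusted p. For genes shared by 4-OI and hemin or opposite between them, the 5 with the largest smaller fold change on each side were named. Genes named for other reasons were chosen after their values were seen: Col1a1, Col3a1, Dcn, Lum, and the examples set side by side for 4-OI and the knockout.

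Overlaps of called genes are given beside the number that independent lists of the same sizes would share. As 2 comparisons with vehicle share its 3 libraries, 20 simulations of unchanged groups against the same controls give the share of equal signs, the correlation and the covariance that sharing alone produces. With only 3 control libraries, they were not divided between comparisons. The mean transcript length of Acod1 was compared between genotypes with an exact two-sided permutation test, chosen after seeing the data. Alternatives were RLE or upper-quartile factors, DESeq2 1.42.0, limma-trend on log2 FPKM with 1 or 0.1 added, no filter, a filter of 10 counts in 6 samples, fits of only the groups compared, a replicate block, a 2-fold threshold, and leaving out each replicate. Leaving out the genes at least 2-fold higher in the knockout, with the simulated covariance of the genes left, was chosen after seeing the data. Terms of the GO process column with 15 to 200 tested genes were tested with camera as well, also chosen after seeing the data. Lengths, FPKM and the annotation columns were not used in the main test, and transcripts named as new by the submitters were not analysed on their own. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.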

Results

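RNA was measured in mouse bone marrow-derived macrophages, cells grown for 7 days from marrow with the growth factor M-CSF. The 12 libraries form 4 groups of 3. Wild-type cells received vehicle for 12 h, 120 µM 4-octyl itaconate (4-OI, an ester of the metabolite itaconate that enters cells) for 15 h, or 15 µM hemin (oxidised iron-containing heme) for 12 h. Cells labelled as Irg1 knockout received vehicle for 12 h. Irg1 is an older name of Acod1, the enzyme that makes itaconate from cis-aconitate. The total of expected counts was 15987792, 22390882 and 10983784 in the wild-type vehicle libraries and 13577690, 17264634 and 12518096 in the Irg1 knockout libraries. It was 13801691, 15691585 and 9868424 in the 4-OI libraries and 9405112, 13606891 and 13771110 in the hemin libraries. Levels are TMM-normalised counts (CPM), scaled to a common library size and given as mean ± SD with n = 3, and fold changes are on the log2 scale with their standard error (SE). The labels do not say whether the 3 replicates of a group came from separate animals or cultures, so p-values measure only the spread between these libraries. The first principal component (52.8% of the variance) separated the knockout libraries from all wild-type libraries, and the second (26.7%) separated the 4-OI libraries from the others.

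The first comparison asks what differed between the cultures labelled Irg1 knockout and wild type, both without added compound. Acod1 itself had 300.0, 240.0 and 333 expected counts in the 3 knockout libraries (21.7, 13.6 and 26.3 CPM) and 462, 705 and 286 in the wild-type vehicle libraries (27.5, 30.5 and 25.01 CPM). Its mean was 20.5 ± 6.4 CPM against 27.7 ± 2.7 CPM, a log2 fold change of -0.48 (SE 0.26, adjusted p = 0.194). Gene-level counts therefore do not separate the genotypes at this locus. The mean length of the Acod1 transcripts behind these counts did: it was 3217 ± 144 nucleotides in the knockout libraries and 2630 ± 16.2 in the 9 wild-type libraries (exact two-sided permutation p = 0.00455, a test chosen after the values were seen). The Acod1 fold change passed the threshold with both FPKM alternatives, at -0.71 with 1 added and -0.79 with 0.1 added (adjusted p = 0.0150 and 0.0221). FPKM divide by the transcript length, so this larger decrease includes the greater length in the knockout libraries and is not separate from it. Acod1 also passed with no filter on low counts (-0.50, adjusted p = 4.38e-09). Over its 15 alternatives the log2 fold change ranged from -0.79 to -0.23, weakest without knockout replicate 2, and the adjusted p from 4.38e-09 to 0.510.

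Among genes with a mean of at least 5 CPM, those with the largest increases in the knockout cultures included several of the extracellular matrix and of marrow stroma. Sfrp1, a secreted Wnt antagonist, was at 23.3 ± 4.7 CPM against 1.01 ± 0.47 CPM in wild-type vehicle (log2 fold change 4.40, SE 0.23). Cxcl12, a chemokine made by marrow stroma, was at 104 ± 12.7 CPM against 9.36 ± 0.31 CPM (3.49, SE 0.10). Ogn and Prelp, small proteoglycans of the extracellular matrix, rose by 3.59 (SE 0.13) and 3.51 (SE 0.32), and Rspo2, Alpl (alkaline phosphatase), Hp (haptoglobin) and Irs1 rose by 3.49, 3.43, 3.43 and 3.30. Cx3cr1, the fractalkine receptor of monocytes and macrophages, was the named gene that fell most, from 194 ± 10.2 CPM to 31.4 ± 3.6 CPM (-2.62, SE 0.09). Smaller decreases were found for Parvg (-1.41), Dtx3l (-1.38), Trem1 (-1.31), Traf3ip3 (-1.30), Atp2a3 (-1.24), Cep85 (-1.21) and Mmp8 (-1.13); no library gave Cep85 a whole expected count, so its reads were shared with other transcripts. Among the genes named in advance, Hmox1 (heme oxygenase 1) had a log2 fold change of 0.08 (SE 0.06, adjusted p = 0.318) and Nqo1, a quinone reductase, rose by 0.59 (SE 0.08, adjusted p = 9.52e-08). In all, 4833 of 12148 tested genes changed at an adjusted p under 0.05, 2850 higher and 1983 lower. Of these, 1400 were at least 2-fold higher and 52 at least 2-fold lower. The 1400 genes held 6.13 ± 0.41% of all counts in the knockout libraries and 1.52 ± 0.10% in wild-type vehicle, and 779 of them had a mean under 5 CPM. Without them, 1450 genes were higher, a count chosen after seeing the data.

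Of the 30 gene lists tested, 6 were called in the knockout. All 8 tested fibroblast and stromal markers rose (8 adjusted over the list alone), with a median log2 fold change of 2.40 (adjusted p = 5.05e-35, and adjusted p = 0.0248 with an estimated correlation). Col1a1 and Col3a1, chains of fibrillar collagen, were at 4850 ± 299 and 1056 ± 60.4 CPM against 816 ± 118 and 132 ± 15.5 CPM, Sparc rose by 2.25 (SE 0.07) and Postn by 1.53 (SE 0.06). The summed level of the list was 12246 ± 724 CPM in the knockout, 2188 ± 238 CPM in wild-type vehicle, 2316 ± 125 CPM with 4-OI and 1996 ± 273 CPM with hemin. Dcn and Lum, the other 2 genes of that list, had at most 9 expected counts in any library and were not tested. The remaining 5 calls were each lost under an estimated correlation, at an adjusted p of 0.356. Integrated stress response genes were mostly higher, 22 higher and 2 lower of 30 (23 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.00151, and adjusted p = 0.356 with an estimated correlation). The serine synthesis enzyme Phgdh rose by 1.37, the mitochondrial folate enzyme Aldh1l2 by 1.88, Nupr1 by 1.61 and Ddit4 by 1.88, in the same libraries in which the stromal markers were raised by a median of 2.40. Mitotic genes were lower, 20 of 20 (20 adjusted over the list alone; median -0.33, adjusted p = 2.26e-05, and adjusted p = 0.356 with an estimated correlation), with Ccnb2 at -0.54 and Cdk1 at -0.32. DNA replication genes were lower in 15 of 19 cases (17 adjusted over the list alone; median -0.19, adjusted p = 0.00275, and adjusted p = 0.356 with an estimated correlation), with Mcm5 at -0.23. Macrophage identity genes were 8 lower and 2 higher of 16 (9 and 2 adjusted over the list alone; median -0.13, adjusted p = 0.00771, and adjusted p = 0.356 with an estimated correlation). Csf1r, the M-CSF receptor gene, fell (-0.22), while Adgre1, which encodes F4/80, rose by 0.33. Glycolysis genes were 7 lower of 18 (7 adjusted over the list alone; median -0.12, adjusted p = 0.0376, and adjusted p = 0.356 with an estimated correlation), with Pdk1 at -0.52 and Hk3 at -0.38. Beside these 4 lower groups, too, the stromal markers stood at a median of 2.40. The neutrophil markers were not called as a list (median -0.75, or -0.39 at its weakest over the settings, adjusted p = 0.0787), nor were NRF2 targets (15 higher and 4 lower of 29, adjusted p = 0.115) or type I interferon genes (14 higher and 1 lower of 28, adjusted p = 0.487); adjusted over the list alone, the higher and lower members were 1 and 3 of 6, 16 and 4 of 29, and 15 and 1 of 28.

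**Figure D1:**
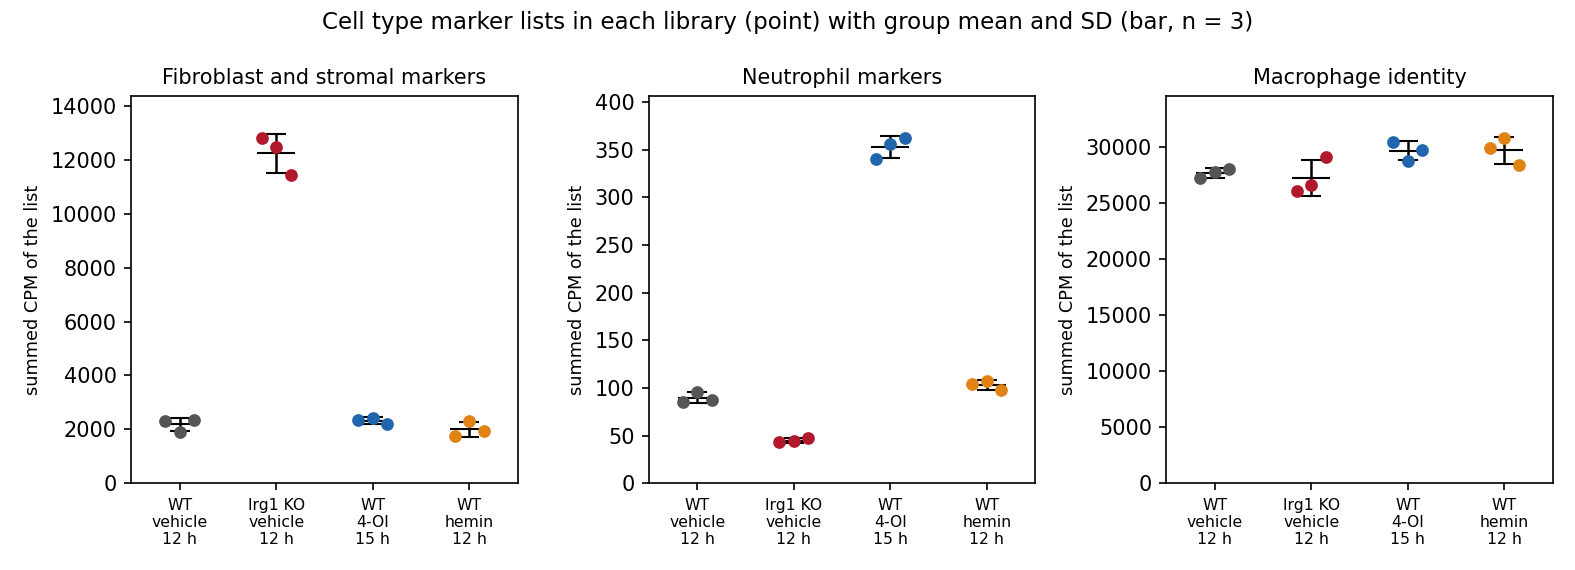
Summed normalised counts (CPM) of the fibroblast and stromal, neutrophil and macrophage identity lists in each of the 12 libraries (points), with group mean and SD (bars, n = 3). The 3 knockout libraries lie between 11434 and 12824 CPM for the stromal list, above the 9 wild-type libraries at 1758 to 2421 CPM.

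The second comparison asks what 4-OI changed in wild-type macrophages. Genes of the antioxidant response were among those that rose. Nqo1 reached 148 ± 5.2 CPM (log2 fold change 2.80, SE 0.07), Hmox1 from 1000 ± 76.0 to 4792 ± 39.2 CPM (2.26, SE 0.06) and Slc7a11, the cystine transporter, from 22.0 ± 0.73 to 791 ± 28.0 CPM (5.17, SE 0.12). Esam, a cell adhesion molecule, went from 0.417 ± 0.24 to 31.9 ± 0.79 CPM (6.08, SE 0.18). Other genes that rose strongly, named by the rule that asks for a mean of at least 5 CPM, were Cdcp1 (5.91), Gsta4, a glutathione transferase (5.76), Il1f9, which encodes interleukin 36 gamma (5.71), the endothelin receptor Ednrb (5.29), Tarm1 (4.51) and Slc16a9 (4.40). That mean is over the 6 libraries compared. In vehicle, Cdcp1, Gsta4 and Il1f9 were at only 0.180, 0.253 and 0.221 CPM, so the size of their fold changes rests on levels near 0. Cx3cr1 fell from 194 ± 10.2 to 4.85 ± 1.07 CPM (-5.36, SE 0.13). The monocyte chemokine genes Ccl12 (-4.87, SE 0.17) and Ccl7 (-4.37, SE 0.08) fell, as did Ifit3 (-3.70), Ifi213 (-3.23), the cholesterol hydroxylase gene Ch25h (-3.10), Cd300e (-2.97) and Usp18 (-2.87). Slc7a11 and Ifit3 had no whole expected counts in any library, so part of their reads was shared with other transcripts. Acod1 was at 35.6 ± 5.6 CPM (0.36, SE 0.25, adjusted p = 0.269); it passed the threshold with no filter (adjusted p = 1.15e-05) and with only the 2 groups compared (adjusted p = 0.00492), and over its 15 alternatives the log2 fold change ranged from 0.21 to 0.45 and the adjusted p from 1.15e-05 to 0.600. In all, 6126 genes changed, 3083 higher and 3043 lower, of which 442 were at least 2-fold higher and 524 at least 2-fold lower. The 4-OI cells were collected at 15 h and the vehicle cells at 12 h, so treatment and hours differ together. The split between directions moved with other settings: upper-quartile factors gave 2739 higher and 3412 lower. Deposited FPKM with 1 added, which changes the unit, the factors and the test together, gave 1743 higher and 4608 lower, with the median of all genes shifted by -0.13.

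Of the 30 lists, 15 were called with 4-OI, and 9 of these held under an estimated correlation. All 29 NRF2 targets rose (29 adjusted over the list alone; median 1.89, adjusted p = 5.99e-123, and adjusted p = 0.000348 with an estimated correlation). Among them were Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (2.88, SE 0.05), Prdx1 (2.77, SE 0.06), Srxn1 (3.53, SE 0.06) and Gss, glutathione synthetase (2.72, SE 0.06). All 28 type I interferon response genes fell (28 adjusted over the list alone; median -1.63, adjusted p = 6.98e-41, and adjusted p = 0.0077 with an estimated correlation), with Ifit2 at -2.80 and Oasl2 at -1.36. All 20 mitotic genes fell (20 adjusted over the list alone; median -1.27, adjusted p = 6.18e-35, and adjusted p = 0.0103 with an estimated correlation), including Top2a (-1.35), Mki67 (-1.23) and Kif11 (-1.61). DNA replication genes fell in 18 of 19 cases (18 adjusted over the list alone; median -0.74, adjusted p = 4.31e-14), with Uhrf1 at -1.06 and Rrm1 at -0.94. Cholesterol synthesis genes rose in 23 of 24 cases (23 adjusted over the list alone; median 0.98, adjusted p = 2.82e-21), among them Fdps (1.53) and Cyp51 (1.04). LXR targets were 10 higher and 3 lower of 13 (10 and 3 adjusted over the list alone; median 0.67, adjusted p = 8.52e-07), with Mylip at 1.98 and Scd2 at 2.04. Glycolysis genes were 11 higher and 2 lower of 18 (11 and 2 adjusted over the list alone; median 0.37, or 0.23 at its lowest over the settings, adjusted p = 1.03e-05), with the glucose transporter Slc2a1 at 1.56, Pkm at 1.07 and Aldoa at 0.90. Heme breakdown and iron storage or export genes were 8 higher and 6 lower of 17 (8 and 6 adjusted over the list alone; median 0.27, or 0.00884 at its lowest over the settings, adjusted p = 0.000311), with Blvrb (biliverdin reductase B) at 1.21 and the iron exporter Slc40a1 at 1.19. Inflammatory mediators were 10 lower and 7 higher of 22 (12 and 7 adjusted over the list alone; median -0.32, adjusted p = 0.00116): Ccl2 (-2.69) and Ccl4 (-2.58) fell, while the neutrophil chemokine Cxcl3 rose by 4.69. The last 6 of the 9 had an adjusted p between 0.0077 and 0.0394 with an estimated correlation.

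The other 6 calls with 4-OI did not hold under an estimated correlation. Heat shock genes were 10 higher of 17 (10 adjusted over the list alone; adjusted p = 0.00361, and adjusted p = 0.0699 with an estimated correlation), with Dnajb4 at 1.53 and Bag3 at 0.92. Ferroptosis and lipid peroxidation genes were 8 higher and 5 lower of 17 (8 and 5 adjusted over the list alone; adjusted p = 0.000343, and adjusted p = 0.0614 with an estimated correlation). Lysosome and autophagy genes were 19 higher and 7 lower of 34 (20 and 7 adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.0811 with an estimated correlation), with Sqstm1, the autophagy receptor p62, at 1.95. Sqstm1 is also in the NRF2 list, so its rise is not separate from that call. Osteoclast genes were 9 higher and 1 lower of 15 (9 and 1 adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.126 with an estimated correlation), with the transcription factor Fos at 1.29. Among neutrophil markers 2 of 6 rose, Mmp8 by 1.97 and S100a8 by 3.69 (2 adjusted over the list alone; adjusted p = 0.000311, and adjusted p = 0.0524 with an estimated correlation). Among endothelial markers 2 of 4 fell, Kdr to -2.52 and Cdh5 to -1.45 on the log2 scale (2 adjusted over the list alone; adjusted p = 0.0453, and adjusted p = 0.155 with an estimated correlation). The summed neutrophil markers stood at 353 ± 11.6 CPM with 4-OI against 89.5 ± 5.7 CPM in vehicle; Mmp8 alone made up 313 ± 16.7 and 79.5 ± 5.3 CPM of these sums.

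The third comparison asks what hemin changed in wild-type macrophages, both groups at 12 h. Genes of heme and iron changed in both directions. Hmox1 rose from 1000 ± 76.0 to 7847 ± 715 CPM (log2 fold change 2.97, SE 0.06) and Slc40a1, which encodes ferroportin, from 489 ± 43.9 to 1906 ± 130 CPM (1.96, SE 0.06). The transferrin receptor gene Tfrc, which takes up iron, fell from 429 ± 9.1 to 101 ± 8.5 CPM (-2.08, SE 0.06). Other genes that rose were Treml4 (2.62), Slc7a11 (2.56), Dnmt3l (2.26), Clec4n (2.20), Tarm1 (2.10) and the formyl peptide receptor Fpr1 (2.04). Decreases were found for Rgs1 (-1.41), Kdr (-1.38), Htr2b (-1.35), Ifit3b (-1.28), Ifit3 (-1.20), Ctla2b (-1.05) and Usp18 (-1.01); Slc7a11, Ifit3 and Ifit3b had no whole expected counts. Acod1 rose from 27.7 ± 2.7 to 84.8 ± 18.2 CPM (1.61, SE 0.23, adjusted p = 0.00137), and Nqo1 rose by 0.80 (SE 0.08). In all, 2092 genes changed, 1152 higher and 940 lower, of which 77 were at least 2-fold higher and 45 at least 2-fold lower. With FPKM and 1 added there were 621 higher and 1422 lower.

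Of the 30 lists, 12 were called with hemin, and 7 held under an estimated correlation. NRF2 targets rose in 27 of 29 cases (27 adjusted over the list alone; median 0.80, adjusted p = 3.54e-158, and adjusted p = 8.76e-05 with an estimated correlation), with Gclm at 1.42, catalase (Cat) at 1.14 and Akr1b8 at 1.09. Heme breakdown and iron storage or export genes were 9 higher and 1 lower of 17 (9 and 2 adjusted over the list alone; median 0.23, or 0.10 at its lowest over the settings, adjusted p = 1.12e-32, and adjusted p = 8.76e-05 with an estimated correlation), with the heme transporter Slc48a1 at 1.17 and the ferritin heavy chain gene Fth1 at 0.88. Type I interferon genes fell in 24 of 28 cases (25 adjusted over the list alone; median -0.48, adjusted p = 1.70e-30, and adjusted p = 0.0144 with an estimated correlation), with Ifit2 at -0.77 and Oasl2 at -0.55. LXR targets rose in 9 of 13 cases (10 adjusted over the list alone; median 0.34, or 0.23 at its lowest over the settings, adjusted p = 5.88e-14, and adjusted p = 0.00921 with an estimated correlation), including the cholesterol exporters Abca1 (0.74) and Abcg1 (1.78). Cholesterol synthesis genes fell in 11 of 24 cases (15 adjusted over the list alone; median -0.19, adjusted p = 4.32e-09, and adjusted p = 0.00921 with an estimated correlation), with Hmgcs1 at -0.57 and Msmo1 at -0.46. Glycolysis genes were 9 higher and 1 lower of 18 (10 and 2 adjusted over the list alone; median 0.16, or 0.10 at its lowest over the settings, adjusted p = 2.06e-06, and adjusted p = 0.0381 with an estimated correlation), with Slc2a1 at 0.84. Ferroptosis and lipid peroxidation genes were 9 higher and 1 lower of 17 (9 and 1 adjusted over the list alone, median 0.29, or 0.11 at its lowest over the settings, adjusted p = 4.09e-06, and adjusted p = 0.0381 with an estimated correlation), with Gss at 0.66. Gss and Slc7a11 are also NRF2 targets in the lists used, so this call is not separate from that of the NRF2 list.

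The remaining 5 hemin calls were lost under an estimated correlation. Mitotic genes were 11 lower of 20 (13 adjusted over the list alone; median -0.19, adjusted p = 2.30e-06, and adjusted p = 0.181 with an estimated correlation), and DNA replication genes were 10 lower of 19 (12 adjusted over the list alone; adjusted p = 0.000377, and adjusted p = 0.111 with an estimated correlation). Macrophage identity genes were 7 higher and 2 lower of 16 (9 and 2 adjusted over the list alone; adjusted p = 0.00342, and adjusted p = 0.181 with an estimated correlation), with the transcription factor Irf8 at 0.71. Endothelial markers were 1 lower of 4, Kdr (1 adjusted over the list alone; adjusted p = 0.00268, and adjusted p = 0.0870 with an estimated correlation). Iron uptake genes were 2 lower and 1 higher of 13 (2 and 1 adjusted over the list alone; adjusted p = 0.00122, and adjusted p = 0.105 with an estimated correlation): Tfrc and the zinc and iron carrier Slc39a8 (-0.74) fell and Slc11a1 rose by 0.53. That list's mean was -0.18 and its test pointed down, while its median lay just above 0 and changed sign with RLE or upper-quartile factors, DESeq2, FPKM and the replicate block.

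**Figure D2:**
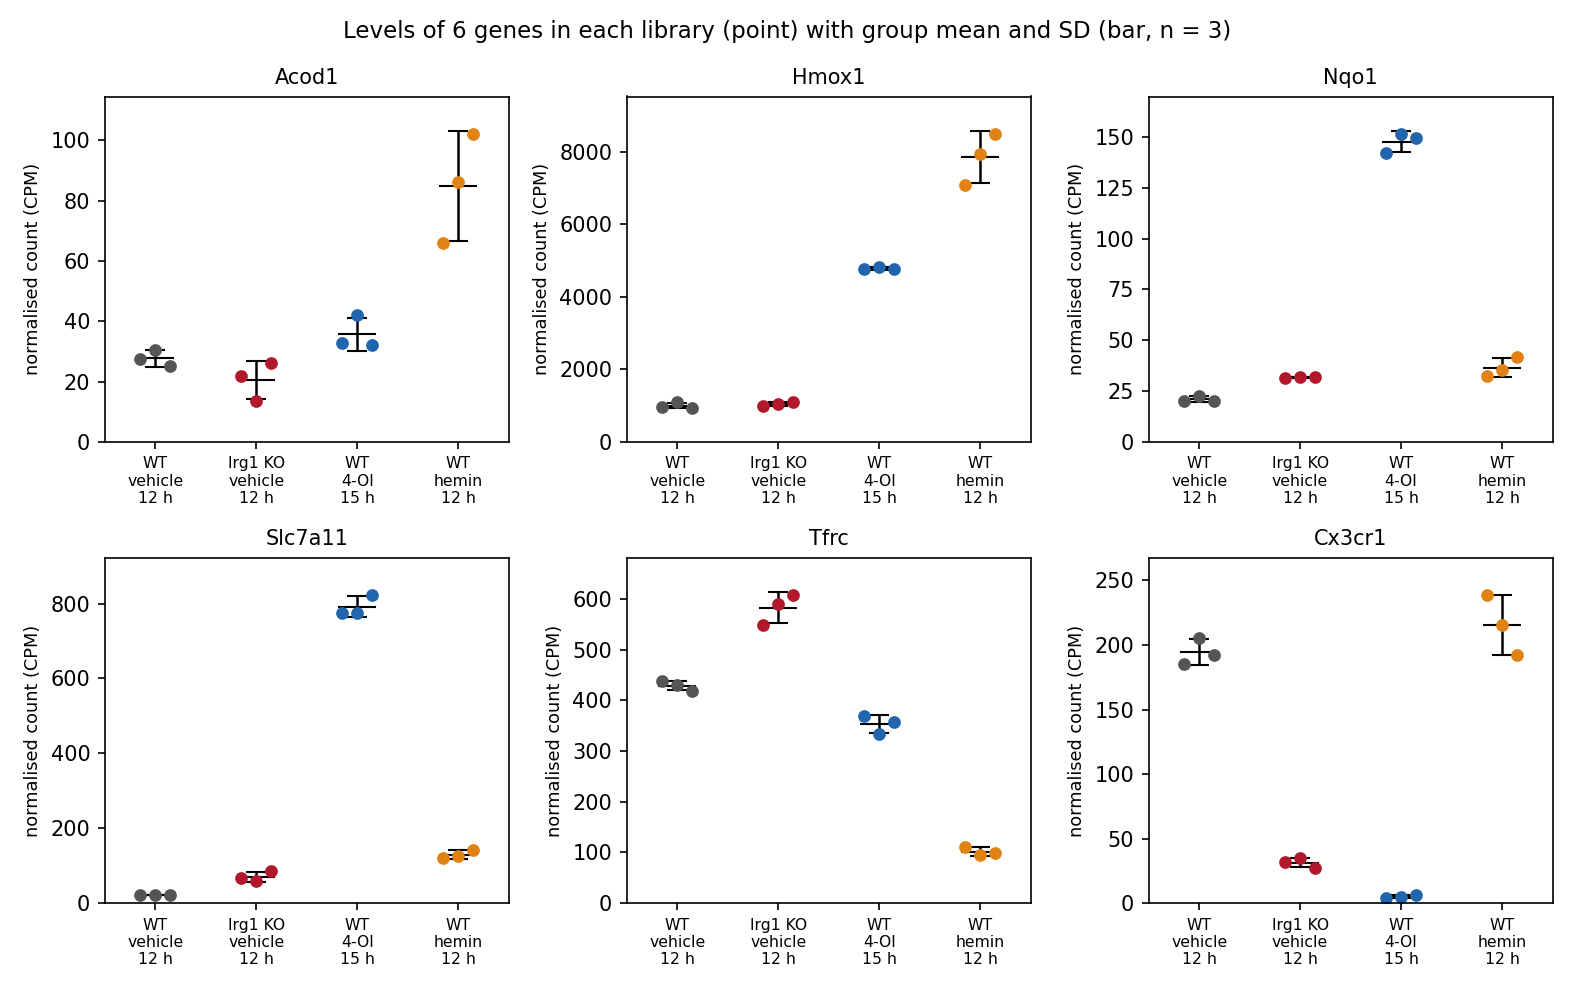
Normalised counts (CPM) of Acod1, Hmox1, Nqo1, Slc7a11, Tfrc and Cx3cr1 in each of the 12 libraries (points), with group mean and SD (bars, n = 3); each panel starts at 0. Hmox1 is highest with hemin at 7847 CPM and Nqo1 with 4-OI at 148 CPM, while Acod1 in the knockout (20.5 CPM) lies near vehicle (27.7 CPM).

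The direct comparison of 4-OI with hemin asks where both compounds differ; they also differ in dose (120 against 15 µM) and hours (15 against 12). Nqo1 was higher with 4-OI by 2.00 (SE 0.07) and Hmox1 lower by a log2 fold change of -0.71 (SE 0.06). Among genes with a mean of at least 5 CPM, those named as most in favour of 4-OI were Il1f9 (5.52), Cdcp1 (4.40), Gsta4 (4.31), Adh7 (3.69), Slc16a9 (3.64), Ednrb (3.40), S100a8 (3.20) and the metalloproteinase Mmp12 (3.03). With hemin, Il1f9, Cdcp1, Gsta4 and Adh7 were at only 0.253, 0.449, 0.680 and 0.934 CPM. The genes named as most in favour of hemin were Cx3cr1 (-5.50), Ccl12 (-3.92), Ccl7 (-3.89), Slc2a6 (-3.22), Cd38 (-2.93), Cd300e (-2.89), Ch25h (-2.67) and Clec4e (-2.64), and Acod1 was lower with 4-OI (-1.25, SE 0.23, adjusted p = 0.00217). In all, 5136 genes differed, 2500 higher and 2636 lower with 4-OI, of which 318 and 364 by at least 2-fold. With FPKM and 1 added, 33.1% of the calls were higher.

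Of the 30 lists, 15 differed between the compounds, and 8 held under an estimated correlation. NRF2 targets were 27 higher and 2 lower of 29 with 4-OI (27 and 2 adjusted over the list alone; median 0.87, adjusted p = 6.12e-58, and adjusted p = 0.00197 with an estimated correlation), with Gclc at 2.43 and Srxn1 at 2.68; the 2 lower ones were Hmox1 and Slc48a1 (-0.21), named after their values were seen. Cholesterol synthesis genes were higher in 23 of 24 cases (23 adjusted over the list alone; median 1.24, adjusted p = 1.86e-50, and adjusted p = 0.00033 with an estimated correlation), with Cyp51 at 1.45. All 20 mitotic genes were lower (20 adjusted over the list alone; median -1.08, adjusted p = 5.53e-38), as were all 28 interferon genes (28 adjusted over the list alone; median -1.30, adjusted p = 9.49e-28) and 18 of 19 DNA replication genes (18 adjusted over the list alone; median -0.51, adjusted p = 1.11e-13). Inflammatory mediators were 10 lower and 4 higher of 22 (10 and 5 adjusted over the list alone; median -0.46, or -0.31 at its weakest over the settings, adjusted p = 4.97e-06), with Ccl2 at -2.46 and Tnf at -1.10. Heat shock genes were 11 higher of 17 (14 adjusted over the list alone; median 0.38, adjusted p = 0.000263), and neutrophil markers were 2 higher and 1 lower of 6 (2 and 1 adjusted over the list alone; adjusted p = 5.28e-05), with Mmp8 at 1.77, S100a8 at 3.20 and Lcn2 at -0.80. Those 6 had an adjusted p of 0.00569 to 0.0325 with an estimated correlation. The Lcn2 call was lost with DESeq2 (adjusted p = 0.0947), without 4-OI replicate 1 or 2 (0.0559 and 0.0826) and without hemin replicate 2 or 3 (0.134 and 0.0973). The other 7 lists were lost under an estimated correlation: glycolysis (0.118), ferroptosis and lipid peroxidation (0.209), LXR targets (0.245), lysosome and autophagy (0.102), macrophage identity (0.228), metal response (0.110) and alternative activation (0.228), each value the adjusted p with an estimated correlation. Alternative activation was lost with the replicate block too (adjusted p = 0.0568). The ferroptosis median, 0.02, changed sign with upper-quartile factors and with FPKM. In that order, their higher and lower members were 10 and 3, 7 and 7, 9 and 4, 17 and 3, 3 and 5, 4 and 0, and 3 and 5. Adjusted over the list alone, they were 13 and 3, 7 and 7, 9 and 4, 18 and 3, 3 and 6, 4 and 0, and 3 and 5. Cx3cr1, at -5.50, is a member of the macrophage identity list, which had a median of -0.05 and a mean of -0.40.

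**Figure D3:**
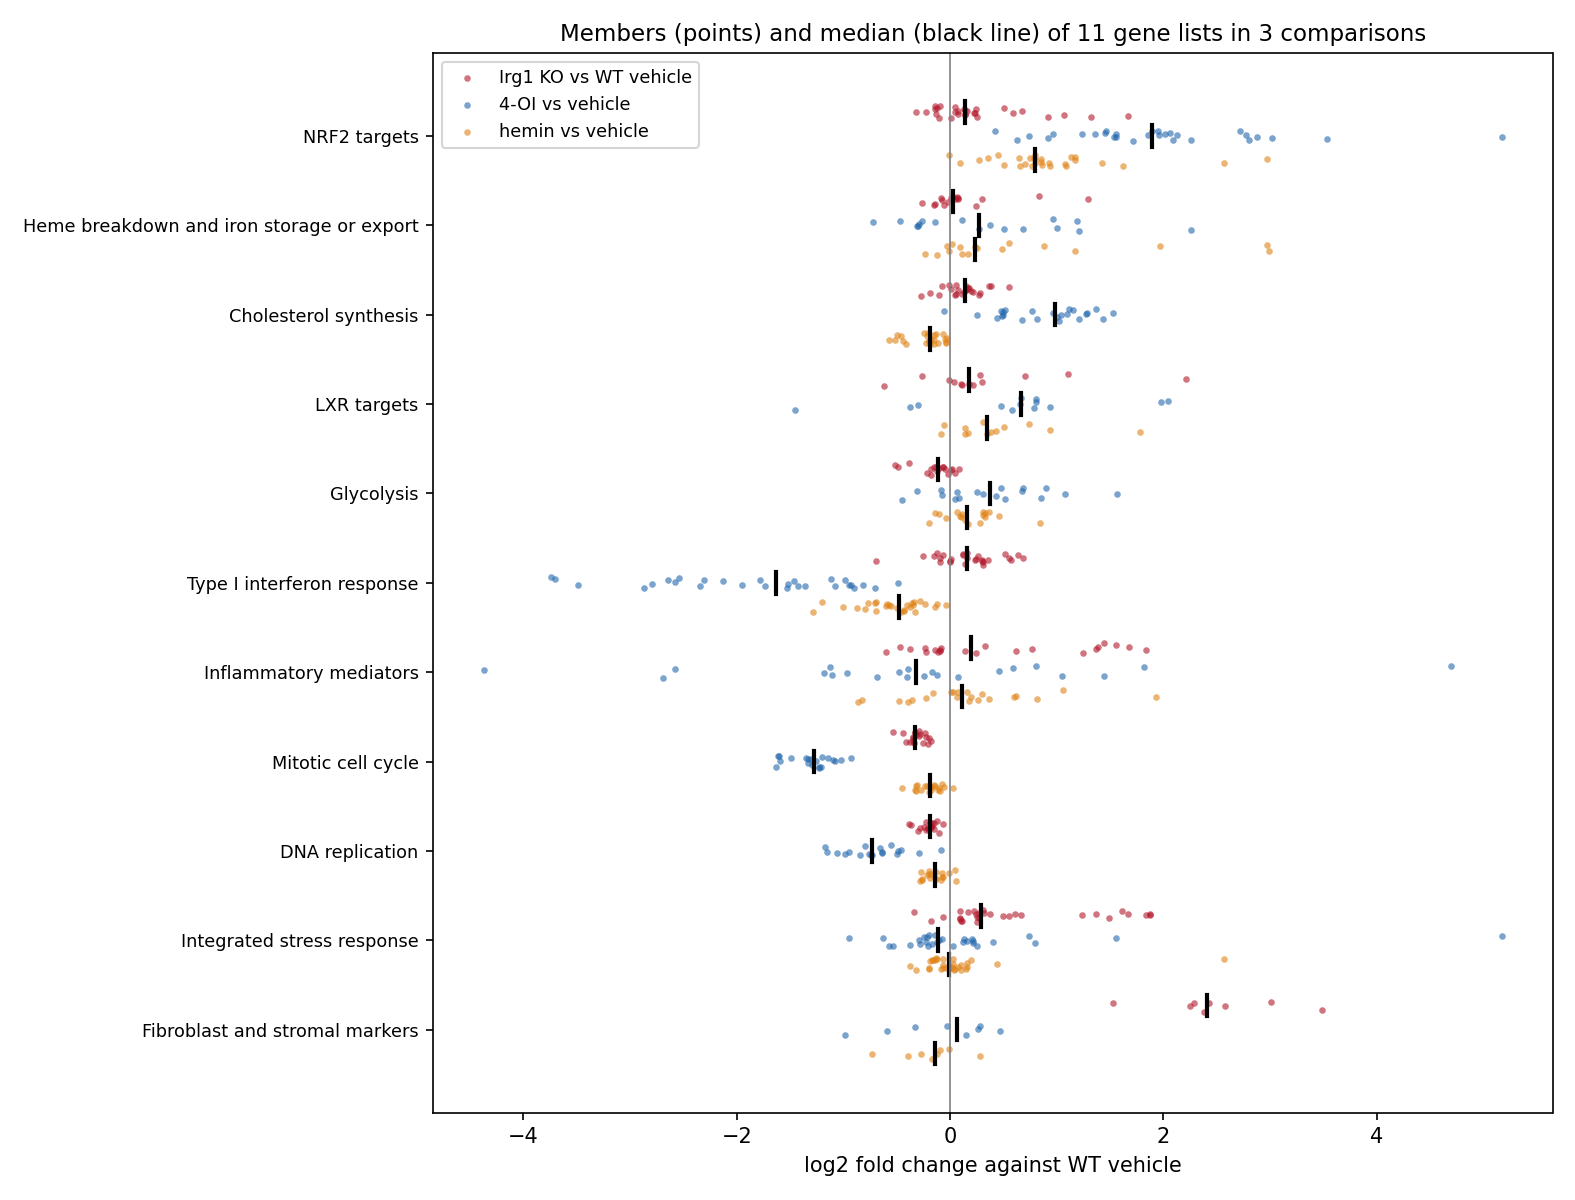
Log2 fold changes against wild-type vehicle of the tested members (points) and their median (black line) for 11 gene lists in the knockout (red), with 4-OI (blue) and with hemin (orange). The NRF2 medians lie at 1.89 with 4-OI and 0.80 with hemin, the cholesterol synthesis medians at 0.98 and -0.19, and the stromal median of the knockout at 2.40.

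Both compounds moved many genes in one direction. Of the genes called with each, 850 were higher with both (292 from independent lists) and 727 lower with both (235 from independent lists), 1577 in all, of which 70 changed at least 2-fold with both. Esam (6.08 with 4-OI and 3.15 with hemin), Slc7a11 (5.17 and 2.56), Dnmt3l (2.85 and 2.26), Hmox1 (2.26 and 2.97) and the lectin gene Clec4n (3.52 and 2.20) were higher with both. Rgs1 (-1.91 and -1.41), Kdr (-2.52 and -1.38), Ifit3 (-3.70 and -1.20), Usp18 (-2.87 and -1.01) and Ccl12 (-4.87 and -0.95) were lower with both. Another 139 genes went opposite ways, against 527 from independent lists. The difference itself was called for each of these genes, which follows largely from picking genes called in opposite directions. Of these, 61 were higher with 4-OI and lower with hemin, such as the stress cytokine gene Gdf15 (0.67 and -0.99), Hmgcs1 (0.76 and -0.57), Idi1 (1.00 and -0.50), Ptgs2 (0.59 and -0.86) and Slit2 (0.50 and -0.52). The other 78 were lower with 4-OI and higher with hemin, such as Clec4e (-1.53 and 1.11), Cd38 (-1.83 and 1.10), Slc2a6 (-2.33 and 0.90), Saa3 (-1.44 and 0.82) and Arl5c (-1.19 and 0.72). The 4-OI calls of Ptgs2 and Slit2 were lost without vehicle replicate 2 (adjusted p = 0.0513 and 0.104). The hemin call of Ptgs2 was lost without hemin replicate 2 (adjusted p = 0.0622), and that of Slit2 without hemin replicate 1 or 3 (0.0933 and 0.165) or vehicle replicate 1 or 3 (0.142 and 0.121). Both comparisons share the 3 vehicle libraries: across the 12148 genes, which are not independent replicates, the correlation of the fold changes was 0.51 (Spearman 0.51), against a mean of 0.44 (Spearman 0.41) and a highest of 0.54 (Spearman 0.43) in 20 simulations of unchanged groups, and 69.6% had the same sign in both, against a mean of 65.3%. The covariance was 0.105, against a mean of 0.0207 and a highest of 0.0301.

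The last comparison asks whether the itaconate ester and the Irg1 knockout moved genes in opposite directions. Both are set against the same 3 vehicle libraries: over all tested genes 62.9% had the same sign in both, against a mean of 65.7% in 20 simulations of unchanged groups with those controls. Of the genes called in both, 1094 were higher and 1045 lower in both (723 and 497 from independent lists), and 692 went opposite ways (1217 from independent lists). Cx3cr1 fell in both (-5.36 with 4-OI and -2.62 in the knockout), and Slc7a11 rose in both (5.17 and 1.67). Mmp8 went opposite ways, at 1.97 with 4-OI and -1.13 in the knockout. The stromal markers, with a median of 2.40 in the knockout, had a median of 0.06 with 4-OI, which turned negative with FPKM (2 higher and 2 lower of 8; 3 and 3 adjusted over the list alone; mean -0.10, adjusted p = 0.768). Of the 1400 genes at least 2-fold higher in the knockout, 468 were called higher and 81 lower with 4-OI (median 0.30). With hemin, 52 of them were higher and 82 lower (median -0.07). These genes were picked against the same vehicle libraries, after seeing the data. Across genes, the correlation of the 4-OI and knockout fold changes was 0.28 (Spearman 0.35), below the simulated means of 0.48 and 0.42 that the shared vehicle libraries give alone. Their covariance was 0.127, against a simulated mean of 0.0219 and a highest value of 0.0316; shared controls add the same covariance with or without real effects, which does not hold for the correlation. For hemin and the knockout the correlation across genes was 0.04, against a simulated mean of 0.47, and the covariance 0.00921, against a simulated mean of 0.0221. Of the genes called with hemin and in the knockout, 310 were higher and 378 lower in both (270 and 153 from independent lists). Another 383 went opposite ways (409 from independent lists).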

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

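All tests in this part were chosen only after the result was seen. The transcript length column, which no comparison of expression used, gave a signal at Acod1: the mean length was 587 nucleotides greater in the knockout libraries (3135, 3382 and 3132 nucleotides) than in the 9 wild-type libraries (2594 to 2653). Of 12010 genes compared, 248 (2.06%) had no overlap between genotypes, where chance gives 0.909%, and the shift at Acod1 exceeded that of 99.9% of 4244 genes with a similar count.

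The pattern to weigh is that reads were assigned to Acod1 in the knockout libraries at 20.5 CPM against 27.7 CPM in vehicle. Wild-type cells or reads mixed into the knockout libraries would keep the wild-type length. The lowest knockout value, 3132 nucleotides, lay above the highest wild-type value, 2653, so such a mix is not the only source of these reads. A mean length does not give the share of reads of wild-type length, so a part from such a mix stays open. A candidate explanation that stays open is an altered Acod1 transcript from the targeted allele. It was drawn from the length difference itself (exact two-sided permutation p = 0.00455, the smallest that 220 arrangements can give), so that difference is no separate test of it. The length is a mean over annotated and assembled transcripts weighted by their share, so it does not show which part of the gene is present. Reads per exon were not used here, and whether a protein is made stays open.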

How the results depend on the processing

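Tests that leave out the genes raised in the knockout were chosen only after the result was seen; all other alternatives were planned. Of 267 named gene results, none reversed under the planned settings; 3977 of the alternative values kept direction and side of the threshold, 5, of Acod1, passed it newly and 19 no longer did. Besides the lost calls given in the report, Slc30a4 between the compounds lost its call with FPKM and 1 added (adjusted p = 0.0504) and without 4-OI replicate 3 (0.0825). With 4-OI, Ptgs2 lost its call with FPKM and 0.1 added (0.0574) and Slit2 with both FPKM alternatives (0.173); with hemin, Slit2 lost it with FPKM and 1 added (0.0751) and with only the groups compared (0.0655). Leaving out single replicates gave 4189 to 4516 called genes in the knockout, 5396 to 5780 with 4-OI, 1549 to 2093 with hemin and 4403 to 4758 between the compounds. A 2-fold threshold lowered the counts by construction: to 1452 (1400 higher, 52 lower) in the knockout, 966 (442 and 524) with 4-OI, 122 (77 and 45) with hemin, 682 (318 and 364) between the compounds, and the overlap of 4-OI and hemin from 1577 to 70. Without the raised genes, 1450 genes were higher in the knockout, fewer by construction. The FPKM alternatives change the unit, the factors and the test together. FPKM hold no TMM factor. These factors were 0.944 to 0.950 for 4-OI, 0.993 to 1.003 for hemin and 1.033 to 1.050 for wild-type vehicle. Leaving them out lowers the fold changes of both compounds, the direction of the shift, though no setting left out the factors alone. With 1 added, FPKM gave 1743 higher and 4608 lower for 4-OI, with 0.1 added 1762 and 4640, with median shifts of -0.13 and -0.14. For hemin it gave 621 higher and 1422 lower with 1 added, and 624 higher with 0.1 added, with median shifts of -0.0587 and -0.0627. Of 48 list calls in 120 tests, 25 held with an estimated correlation; the cause was not tested. The direction of the 4-OI iron uptake list, not called, reversed with RLE factors (adjusted p = 0.993); the cause was not tested. The correlation of 4-OI and knockout fold changes across genes, 0.278, was 0.2998 to 0.305 without single vehicle replicates, 0.267 for genes of at least 5 CPM and 0.291 without the raised genes; the cause was not tested. Replicate numbers did not pair the libraries: deviations from the group means correlated at -0.08 to 0.07 for the same number, and a replicate block gave 4879, 6156, 2159 and 5181 called genes. With that block 47 list calls were left, and alternative activation between the compounds was lost (adjusted p = 0.0568 with camera). In simulated data with 200 planted genes, 66 to 80% of genes with a log2 fold change of 0.5 were found. Far more genes were called in each real comparison, a setting that the simulation did not cover.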

Other observations

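All tests in this part were chosen only after the result was seen, except that of linked DNA around Acod1. Process terms from the annotation columns, 1245 in all, added groups that the fixed lists do not hold, each with its adjusted p under an estimated correlation, which ended every call named here. In the knockout, 35 of 41 genes of collagen fibril organization were higher and 1 lower (median 1.91, adjusted p = 7.70e-50, and adjusted p = 0.0803 with an estimated correlation), beside stromal markers at a median of 2.40. Of 29 genes of blood vessel morphogenesis, 21 were higher and 2 lower (median 1.32, adjusted p = 5.95e-16, and adjusted p = 0.0803 with an estimated correlation). Genes of mRNA splicing via the spliceosome were lower in 41 and higher in 3 of 142 cases (median -0.10, adjusted p = 0.000505, and adjusted p = 0.0921 with an estimated correlation). With 4-OI, 15 of 25 genes of triglyceride metabolism were higher and 4 lower (median 0.33, adjusted p = 4.36e-06, and adjusted p = 0.0921 with an estimated correlation). With hemin, 7 of 15 genes of cholesterol efflux were higher and 0 lower (median 0.19, adjusted p = 4.98e-07, and adjusted p = 0.303 with an estimated correlation), and 9 of 16 genes that regulate viral entry were lower and 0 higher (median -0.27, adjusted p = 0.00359, and adjusted p = 0.449 with an estimated correlation). Between the compounds, 7 of 15 genes of lymphocyte chemotaxis were lower and 2 higher with 4-OI (median -0.23, adjusted p = 2.79e-07, and adjusted p = 0.0506 with an estimated correlation).

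The first pattern is the 1400 genes at least 2-fold higher in the knockout cultures. A lower share of macrophages would raise the markers of every other cell type alike. The neutrophil markers had a median of -0.75 (-0.39 at its weakest over the settings, -0.37 leaving out 1 member). Mmp8, the only neutrophil marker over 5 CPM in vehicle, stood at -1.13 (SE 0.06). Its level was 294 to 326 CPM in the 4-OI libraries and 76.0 to 85.6 CPM in wild-type vehicle. It thus changed with treatment and need not follow the number of neutrophils. The summed mast cell and basophil markers were higher, at 3.13 ± 0.83 against 1.30 ± 0.34 CPM, as were the dendritic cell markers (1.67 ± 0.42 against 0.644 ± 0.062 CPM) and erythroid markers (0.0986 against 0.0740 CPM). The B cell (1.29 against 1.93 CPM), T and NK cell (4.23 against 4.55 CPM) and endothelial markers (32.5 against 36.6 CPM) were lower. These sums were not tested and most are low, so they do not decide whether the share of macrophages differed. DNA linked to the targeted allele that changed only its own genes would place them near Acod1. Of the raised genes, 3.43% lay on the chromosome of Acod1 against 3.31% of tested genes (Fisher's exact p = 0.751). That chromosome holds 400 tested genes, against 1398 raised genes with a position. Its genes could therefore not be most of the raised ones, whatever the outcome. The share can show only whether raised genes were enriched there. Among the 40 nearest tested genes by order, 15% were raised, against 11.6% of tested genes with a position. Linked DNA that affects genes elsewhere was not tested. More stromal cells may be a source. The 8 tested markers had a median of 2.40, and their sum was higher in each knockout library than in any wild-type library. This candidate was drawn from those raised markers, so they are no separate test of it. Stromal cells as a source would have to be of a kind low in Dcn and Lum. These genes together reached at most 0.0127% of the Col1a1 counts in the knockout. All 8 tested markers exceeded 5 CPM in wild-type vehicle too, none is in another list, and the labels name no sort. An effect of the targeted Acod1 allele itself, or a difference between the marrow cultures of both genotypes, cannot be separated from this in 1 comparison of 3 with 3 libraries.

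The second pattern is the positive covariance of the fold changes of 4-OI and of the knockout; their correlation, 0.278, lay below the 0.482 that shared controls gave on average in simulations. The covariance is weighed here because shared controls add the same amount to it with or without real effects. The shared vehicle libraries are not its whole source, since the covariance of 0.127 exceeded the highest of 20 simulations, 0.0316. The raised genes are not its whole source either, since the covariance without them was 0.0538, above the highest of the simulations over the same 10748 genes, 0.0268; the correlation, 0.278 with them, was 0.291 without. An effect of the added compound and of the targeted allele on common genes may remain, and no test here separates it from the longer hours of the 4-OI cells or from a difference between the cultures.

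For each comparison, the 6 libraries allow 10 splits into 3 and 3, and 1 of them, the real one, gave a count as large, so the share of splits cannot go under 0.05. In edgeR fits of those 6 libraries alone, the real split called 4967 genes in the knockout, 6122 with 4-OI, 1843 with hemin and 4988 between the compounds. The highest count of any other split was 0 in each. At an unadjusted p under 0.05 it was 195, 152, 612 and 195, against 5847, 6677, 3300 and 5840 for the real splits. Every other split mixes both groups, so the difference between the groups enters its spread and few calls follow by construction. These counts therefore do not measure what chance gives.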
